A study of Mus musculus with 10 samples.

How the data were processed

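Bulk RNA-seq was done on bone marrow HSPCs of irradiated C57BL/6 mice, 5 libraries with saline and 5 with EGF. Per the labels' protocols, RNA was extracted with the Qiagen RNeasy Micro kit, and libraries were made with a Clontech kit after depletion of rRNA and amplified by PCR. The instrument was a NextSeq500 per the series' design text. The submitters' processing notes name bcl2fastq 2.17, STAR and the builds GRCm38 and mm10. The counting tool, its strand setting, the annotation release, the sort gate and the dose schedule of EGF are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping gene on the other strand cannot be told apart.

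The deposited values are whole-number counts of reads per gene with no normalization, 1 file per library, each with the same 55573 Ensembl gene identifiers. Of these, 55480 are in GENCODE release M21 (GRCm38), which gave positions, exon overlaps and transcript lengths. No row lacked a gene. The files' symbol columns differed in 27 symbols that a spreadsheet had turned into dates or times, and these were replaced by the GENCODE names of the same identifiers. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom between 6.51 and 102). So did pairs across the groups (5.48 to 114), so none was a repeat of another. The closest pair of all was Saline replicate 2 with EGF replicate 1 (5.48), across the groups. PCR copies cannot be told apart in these counts, so statements on depth cover counting error only.

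The main test was edgeR 4.0.16 (R 4.3.3): TMM scaling, genes kept by filterByExpr with its minimum count of 10, the quasi-likelihood F test of EGF against saline over all 10 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors of log2 fold changes were taken from the F statistic. CPM values are scaled by TMM. Gene lists, 35 tested, were written before the data were examined and tested with camera of limma 3.58.1 at its preset correlation of 0.01; 846 of 847 list entries matched a gene. Camera with an estimated correlation, camera on ranks and fry were alternatives. The mean log2 CPM of a list used a prior count of 2. Library measures were compared by exact two-sided permutation tests over all arrangements (scipy 1.17.1), for which the smallest p is 0.0079.

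Genes were named by a rule fixed before the data were examined. In each direction the rule took the 12 named genes with the smallest p among those that passed, or, where fewer than 5 passed, the 5 with the smallest unadjusted p; from each list it took up to 4 members with the smallest p and any that passed; and it always took Egfr, Bbc3, Cdkn1a, Bax, Mdm2, Prkdc, Lig4, Xrcc4, Xrcc6, Kit, Ly6a, Procr, Flt3 and Mki67, and 1 gene that is not reported here. The report gives leading members of some lists, and not every gene that the rule took.

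Depth was similar in all libraries, 6805106 to 8370820 counts. On simulated counts with the dispersions of the 10 libraries, 20% of genes changed 1.5-fold, 52% of those changed 2-fold, 68% of those changed 4-fold and 86% of those changed 8-fold were recovered (50 genes each among 12874), with 4 false calls. With EGF replicate 5 left out, the shares were 38%, 68%, 94% and 98% among 13104 genes, with 5 false calls. By these shares, changes of single genes under 2-fold would often be missed at this number of libraries. In each setting all libraries were drawn with the same dispersion per gene. In the data EGF replicate 5 stood apart, so the shares may not hold for the real test with it. A simulated shift of the interferon list was recovered in both settings with 0 false lists. Genes were simulated as independent there, so this cannot show how camera's preset correlation fares where genes of a list move together. The estimated correlation was 0.362 in the interferon list and 0.446 in the ribosomal list.

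Alternatives fixed beforehand were other scalings (RLE, library size, upper quartile), DESeq2 1.42.0, limma-voom with and without sample quality weights, no filter, a filter of 1 CPM in 5 libraries, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a robust fit, and each library left out in turn. After the data were seen, fits without EGF replicates 3 and 4, without replicates 3 to 5, and without replicate 5 combined with other choices were added, and so were 5 measures of library composition. With all 10 libraries the median log2 fold change of all genes stayed between -0.08 and -0.002 under the scalings and tests tried. Without EGF replicate 5 it was 0 by edgeR and 0.008 by DESeq2. All deposited libraries were used in the main test.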

Results

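RNA was sequenced from hematopoietic stem and progenitor cells (HSPCs), the marrow cells from which blood is renewed. They came from C57BL/6 mice, 16 weeks of age per the labels, at 6 weeks after 500 cGy of whole-body irradiation. Libraries of 2 groups were compared: 5 from mice given saline under the skin and 5 from mice given epidermal growth factor (EGF), the ligand of the receptor EGFR, by the same route. The comparison asks how the transcriptome of these cells differs with EGF after radiation injury. Total counts ranged from 6805106 to 8370820 per library, over 55573 annotated genes, of which 26950 had a count in at least 1 library. Between 18734 and 20046 genes had a count in each of 9 libraries, and 12731 did in EGF replicate 5. Along the main axis of spread between those 9 (first principal component, 24.7% of the variance), EGF replicates 3 and 4 lay at 34.7 and 44.3. EGF replicates 1 and 2 lay at 0.53 and -6.59, and the saline libraries from -29.7 to -2.99. This axis thus did not separate the groups completely. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these libraries, which may be technical.

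Cd69, an early activation antigen of leukocytes, was the gene that rose with EGF by edgeR. Its level was 213 ± 18 CPM (counts scaled by library size; SD, n = 5) with EGF against 120 ± 11.9 CPM (SD, n = 5) with saline, a log2 fold change of 0.83 (SE 0.09), and all 5 EGF libraries lay above all 5 saline libraries. Next among named genes, in the ranking by p, came some that did not pass edgeR's test but separated the groups completely: the chemokine gene Ccl3, the antiproliferative gene Btg2, Nlrc5, a transactivator of MHC class I genes, and the nuclear receptor gene Nr4a2. In the lower direction the leading named genes, none of which passed edgeR's test, were the immunoglobulin heavy-chain variable genes Ighv1-75 and Ighv2-3, Gatm of creatine synthesis, Pgd of the pentose phosphate pathway and Serpinb1a, an inhibitor of neutrophil proteases. All 5 EGF libraries lay below all 5 saline libraries for each of these. The named genes of both directions were picked by p over these same libraries, so their separation is partly due to that choice. DESeq2 called Ccl3 (adjusted p = 0.000223), Btg2 (0.0135), Nlrc5 (0.0214) and Nr4a2 (0.0129) higher. It called Ighv1-75 (1.01e-06), Gatm (0.00499), Ighv2-3 (0.0129) and Pgd (0.0129) lower. Limma-voom with quality weights called Ccl3, Btg2, Nlrc5, Ighv1-75 and Gatm.

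By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 12874 genes, 1 gene was higher with EGF, Cd69 (adjusted p = 0.0226), and 0 were lower. At an unadjusted p under 0.05 there were 790 higher and 352 lower genes, 8.87% of those tested. DESeq2 called 13 higher and 15 lower, limma-voom called 1 and 0, and limma-voom with sample quality weights called 8 and 4. The libraries of the groups did not overlap for 421 genes, 3.27% of those tested, where chance gives 0.79%. Cd69 had an adjusted p between 0.0884 and 0.175 when any 1 of Saline replicates 1, 3, 4 and 5 or EGF replicates 2, 3 and 4 was left out, with a log2 fold change between 0.78 and 0.84. Without EGF replicate 5 the test called 4 genes higher and 4 lower among 13104.

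Cd69 lies on chromosome 6 from 129267325 to 129275436 (GRCm38), on the minus strand, and no exon of another annotated gene overlaps its exons. Ccl3, on chromosome 11 from 83647844 to 83649355, was at 48.0 ± 4.39 CPM with EGF and 26.9 ± 4.73 CPM with saline (log2 fold change 0.84, SE 0.14, edgeR adjusted p = 0.402; SD, n = 5 each). Btg2, on chromosome 1 from 134075170 to 134079120, was at 170 ± 24.6 CPM against 111 ± 11.3 CPM. Nlrc5, on chromosome 8 from 94434356 to 94527272, was at 155 ± 18.7 CPM against 107 ± 11.4 CPM, and an antisense transcript overlaps 0.9% of its exonic bases. Nr4a2, on chromosome 2 from 57106830 to 57124003, was at 74.4 ± 20.3 CPM against 36.5 ± 7.51 CPM (log2 fold change 1.03, SE 0.21). The edgeR adjusted p was 0.402 for Btg2 and Nlrc5 and 0.50 for Nr4a2.

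Gatm, on chromosome 2 from 122594467 to 122611303, was at 32.2 ± 3.16 CPM with EGF and 51.1 ± 6.97 CPM with saline (log2 fold change -0.66, SE 0.13; SD, n = 5 each). Pgd, on chromosome 4 from 149149991 to 149166771, was at 57.8 ± 4.09 CPM against 83.9 ± 10.4 CPM (log2 fold change -0.54, SE 0.10). Serpinb1a, on chromosome 13 from 32842092 to 32851185, was at 93.8 ± 7.94 CPM against 124 ± 9.90 CPM. Ighv1-75, on chromosome 12 from 115833950 to 115834418, had 27 to 119 counts in the saline libraries and 0 to 8 in the EGF libraries. Ighv2-3, on the same chromosome from 113611187 to 113611617, had 45 to 810 counts with saline and 0 to 26 with EGF. Heavy-chain variable genes are near copies of one another and differ between clones of B cells, so their counts are uncertain. The edgeR adjusted p was 0.402 for Gatm, Pgd and both variable genes and 0.552 for Serpinb1a.

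**Figure D1:**
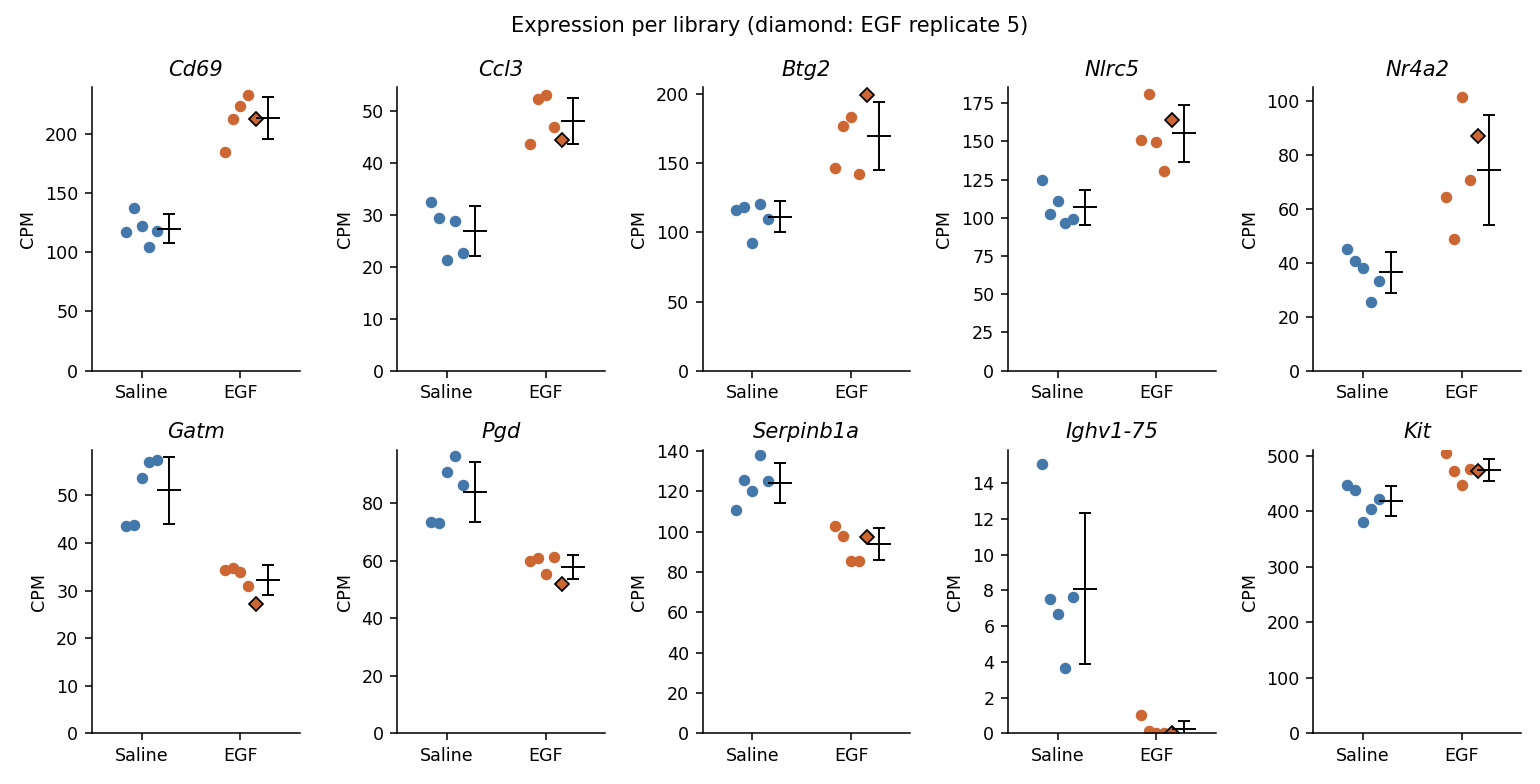
CPM, scaled by TMM, of 10 named genes in each library (vertical axes, linear from 0), with saline libraries in blue and EGF libraries in orange; the bar and whiskers beside each group are its mean and SD (n = 5), and the diamond is EGF replicate 5. Cd69 passed edgeR's test across all genes, at 213 CPM with EGF and 120 CPM with saline. The other 9 did not, though DESeq2 called all of them but Serpinb1a and Kit.

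Without EGF replicate 5, the 4 genes called higher were Cd69, Ccl3, Rgs1, a regulator of G protein signalling, and Gimap6, a GTPase of immune cells. Rgs1 was at 234 ± 22.1 CPM (SD, n = 4) against 158 ± 12 CPM (SD, n = 5; log2 fold change 0.57, SE 0.07), and Gimap6 at 155 ± 15.4 CPM against 107 ± 7.33 CPM (log2 fold change 0.54, SE 0.08). The 4 called lower were Ighv1-75, the non-coding AI506816, Tgfbi, an extracellular matrix gene induced by TGF-beta, and Prom1, which encodes the surface antigen CD133. Tgfbi fell from 29.6 ± 5.45 to 14.6 ± 2.19 CPM, Prom1 from 7.89 ± 3.15 to 1.89 ± 0.331 CPM and AI506816 from 249 ± 8.37 to 184 ± 8.20 CPM. Their edgeR adjusted p lay between 0.0029 for Cd69 and 0.0414 for Prom1. Rgs1, Gimap6, AI506816, Tgfbi and Prom1 were named after their values were seen. In the left-out EGF replicate 5, Rgs1 was at 106 CPM, below all saline libraries, and Gimap6 at 101 CPM, within the saline range. For the rest of the called genes that library lay on the same side of saline as the other EGF libraries. With all 10 libraries the log2 fold change was 0.40 for Rgs1 and 0.44 for Gimap6 (edgeR adjusted p = 0.552 each).

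Egfr itself was barely sampled in these cells, with 0 to 2 counts per library, and was left out of the test by the filter on low counts. No gene of the p53 response and DNA end joining that was fixed for naming passed the edgeR test. Bbc3, which encodes the p53-induced killer PUMA, was at 4.85 ± 2.89 CPM with EGF and 5.49 ± 1.51 CPM with saline (SD, n = 5 each; log2 fold change -0.18, SE 0.63). Cdkn1a, the p21 inhibitor of cell division, had a log2 fold change of 0.26 (SE 0.20), Mdm2, the ubiquitin ligase of p53, 0.22 (SE 0.16), and Bax, a pore-forming killer, -0.54 (SE 0.69). For the end-joining genes the values were 0.07 (SE 0.10) for Prkdc, -0.44 (SE 0.70) for Lig4, 0.38 (SE 0.36) for Xrcc4 and 0.16 (SE 0.10) for Xrcc6. Adjusted p lay between 0.610 for Xrcc6 and 0.923 for Bbc3. EGF replicate 5, in which Bax and Lig4 had 0 counts, set the sign for Bbc3 and Xrcc4, at 0.13 and -0.09 without it. Without it the values were also smaller for Bax (-0.21), Lig4 (-0.12), Mdm2 (0.05), Xrcc6 (0.07) and Prkdc (0.03).

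Stem and progenitor cell genes also gave no call by the edgeR test. Kit, the stem cell factor receptor, was at 475 ± 20.4 CPM with EGF and 419 ± 27.0 CPM with saline (SD, n = 5 each; log2 fold change 0.18, SE 0.07, adjusted p = 0.552). The receptor gene Flt3 of lymphoid-primed progenitors was at 218 ± 31.8 against 219 ± 44.2 CPM, Ly6a, which encodes Sca-1, at 13.3 ± 7.06 against 14.6 ± 2.05 CPM, Procr, the endothelial protein C receptor of stem cells, at 8.26 ± 5.52 against 10.2 ± 1.90 CPM, and the proliferation gene Mki67 at 1739 ± 323 against 1551 ± 82.5 CPM. Among the 28 HSC marker genes tested, Ifitm1 passed when adjusted over the list alone, at 41.1 ± 7.38 against 63.6 ± 6.90 CPM, and none passed over all genes by edgeR, while DESeq2 called Ifitm1 (adjusted p = 0.0368). Hoxa9 (log2 fold change 0.41, SE 0.13), Meis1 (0.34, SE 0.12) and Angpt1 (0.50, SE 0.19) had an edgeR adjusted p of 0.552 each. The log2 fold change without EGF replicate 5 was 0.27 for Angpt1 and 0.04 for Mki67, against 0.17 with it, while Ly6a (0.05), Procr (0.03) and Flt3 (0.03) turned from below to above 0.

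By camera at its preset correlation, 4 lists were higher with EGF: interferon response, NF-kB and inflammation, ERK-responsive genes and mitochondrially encoded genes. Of 36 interferon response genes, 33 had a log2 fold change above 0, with a median of 0.56 (camera adjusted p = 2.73e-11 over 35 lists). Of 21 NF-kB and inflammatory genes, 17 did, with a median of 0.35 (camera adjusted p = 0.0001). Of 36 ERK-responsive and immediate early genes, 22 did, with a median of 0.06 and a mean of 0.22 (camera adjusted p = 0.0021). Of 8 mRNAs encoded by the mitochondrial genome, 7 did, with a median of 0.29 (camera adjusted p = 0.0049). With an estimated correlation none of these calls held: the adjusted p was 0.387, 0.0546, 0.387 and 0.435. The NF-kB list passed fry, which asks whether its genes move on balance one way (adjusted p = 0.0038), and the other 3 did not (0.195, 0.233 and 0.276).

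The interferon genes with the smallest p were Xaf1, at 16.0 ± 6.56 against 8.18 ± 0.811 CPM, the antiviral GTPase gene Mx1, at 19.8 ± 26.7 against 2.93 ± 1.45 CPM, Parp14, at 102 ± 23.1 against 74.2 ± 8.41 CPM, and Cmpk2, at 22.7 ± 7.59 against 13.7 ± 1.73 CPM (SD, n = 5 each). EGF replicate 2 had the highest mean of the list, 1.15 on the log2 scale above the saline mean, where the other EGF libraries had 0.18 to 0.40; the list's median was 0.35 without it (camera adjusted p = 0.0001). With all 10 libraries no interferon gene passed edgeR over all genes or adjusted over the list alone. Without EGF replicate 5, 17 of 36 passed adjusted over the list alone and 0 over all genes. The log2 fold change of Mx1 was then 1.44, against 2.75 with that library. With all 10 libraries DESeq2 called Ccl3 and Ptgs2 of the NF-kB list over all genes (adjusted p = 0.0319 for Ptgs2). In that list 3 genes passed edgeR adjusted over the list alone and 0 over all genes. Its leading members were Ccl3, Tnfaip3, a feedback inhibitor of NF-kB (log2 fold change 0.56, SE 0.13), and the cyclooxygenase gene Ptgs2 (0.70, SE 0.19). In the ERK list 4 passed edgeR adjusted over the list alone and 0 over all genes, where DESeq2 called Btg2 and Nr4a2; the list was led by Btg2, Nr4a2, Fosl2 (0.71, SE 0.17) and Nr4a1 (0.80, SE 0.21). For the mitochondrial list, mt-Co1 had 0.39 (SE 0.13), and the call was lost without EGF replicate 4 (camera adjusted p = 0.0528, median 0.23). The median of the ERK list ranged from 0.03 to 0.14 with any 1 library left out, lowest without Saline replicate 3 and highest without EGF replicate 5. Over 1.5 times the full value it also came to 0.12 without Saline replicate 2, 0.13 without Saline replicates 1 or 5, and 0.09 without EGF replicates 1 or 2. Without EGF replicates 3 and 4 the ERK and mitochondrial calls were lost (camera adjusted p = 0.153 and 0.424, medians 0.04 and 0.11). With EGF replicate 5 left out as well, both were kept (camera adjusted p = 0.0026 and 0.0023, medians 0.10 and 0.16). That fit held EGF replicates 1 and 2 only, and camera called 9 lists higher in it, so a kept call is weak support. Without EGF replicate 5 alone, 6 NF-kB, 6 ERK and 7 mitochondrially encoded genes passed edgeR as higher adjusted over their lists alone. In the NF-kB list 1 gene passed as lower there.

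By camera at its preset correlation, 9 lists were lower with EGF, 7 of them of translation, metabolism, stress and histones and 2 of blood cell types. Of 51 cytosolic ribosomal protein genes, 49 had a log2 fold change below 0, with a median of -0.23 (camera adjusted p = 2.08e-12). Of 46 oxidative phosphorylation genes, 42 did, with a median of -0.26 (camera adjusted p = 4.72e-06), and of 20 glycolysis genes, 15 did, with a median of -0.17 (camera adjusted p = 0.0035). Of 22 cholesterol synthesis genes, 19 did (median -0.36, camera adjusted p = 0.0018), of 20 antioxidant genes, 17 did (median -0.22, camera adjusted p = 0.0008), and of 11 heat shock genes, 8 did (median -0.17, camera adjusted p = 0.0172). Of 21 replication-dependent histone genes, 18 did, with a median of -0.33 (camera adjusted p = 2.33e-05). With an estimated correlation the adjusted p of these 7 lists, in that order, was 0.405, 0.387, 0.273, 0.435, 0.387, 0.387 and 0.435, so no call held. By fry, glycolysis passed (adjusted p = 0.0282) and the others had 0.117 to 0.233.

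The leading members of these lists were Rpl35 (log2 fold change -0.27, SE 0.08) and Rps2 (-0.37, SE 0.12) for the ribosome, Uqcrq (-0.43, SE 0.12) and Cox7b (-0.28, SE 0.10) for the respiratory chain, and Eno1 (-0.48, SE 0.11) and Ldha (-0.45, SE 0.12) for glycolysis. Exons of genes on the other strand overlap 71.2% of the exonic bases of Rpl35, so its counts are uncertain. Among the others were Ebp (-0.74, SE 0.32) and Msmo1 (-0.45, SE 0.21) of cholesterol synthesis, Sod2 (-0.24, SE 0.09), Hspa1a (-3.11, SE 0.80), Hspe1 (-0.54, SE 0.20), Hist1h4d (-0.42, SE 0.15) and Hist1h4h (-0.52, SE 0.20). None passed edgeR over all genes, where DESeq2 called Hspa1a (adjusted p = 0.0214) and Pgd of the antioxidant list, and adjusted over the list alone 2 glycolysis genes, 1 antioxidant gene and 1 heat shock gene passed edgeR. Without EGF replicate 5, 16 ribosomal, 4 oxidative phosphorylation, 8 glycolysis, 3 antioxidant and 4 heat shock genes passed edgeR adjusted over the list alone. No cholesterol synthesis or histone gene did, and none of these lists had a gene that passed over all genes. The heat shock list means of Saline replicates 1 and 2 (-0.41 and -0.35) lay within the EGF range of -0.75 to -0.26, against 0.24 to 0.27 in the other saline libraries. Hspa1a had 7 and 17 counts in those 2, 49 to 93 in the other saline libraries and 1 to 12 with EGF. Near-identical copies of histone, ribosomal and Hspa1 genes share reads, so single members are uncertain. EGF replicates 3, 4 and 5, which also had the highest Malat1 shares, had the ribosomal list's lowest means. Without these 3 libraries the medians were -0.07 for the ribosome, -0.13 for oxidative phosphorylation, -0.13 for antioxidant genes and -0.09 for histones, with the camera calls kept. The median was -0.05 for cholesterol synthesis (camera adjusted p = 0.0516). In that fit, with EGF replicates 1 and 2 only, camera called more lists than with all 10 libraries, so a kept call is weak support. Without EGF replicates 3 and 4 alone the histone, glycolysis and heat shock calls were lost (camera adjusted p = 0.0594, 0.0594 and 0.164). Without EGF replicate 5 the cholesterol median was -0.21, and the heat shock call was lost without Saline replicate 3, EGF replicate 1 or EGF replicate 3 (camera adjusted p = 0.0615, 0.0992 and 0.110). It was also lost by camera on ranks with all 10 libraries (adjusted p = 0.0590).

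Lists of neutrophil and granule genes and of plasma cell genes were the cell type lists that camera, at its preset correlation, called lower with EGF. Of 17 neutrophil and granule genes, 11 had a log2 fold change below 0, with a median of -0.63 (camera adjusted p = 0.0001), and 4 passed edgeR adjusted over the list alone, all of them expressed in immature granulocytic cells: the granule protease genes Prtn3 (101 ± 29.1 against 219 ± 71.9 CPM), Elane (150 ± 42.7 against 283 ± 118 CPM) and Ctsg (100 ± 18.3 against 176 ± 60.4 CPM), and Ms4a3 of granulocyte-monocyte progenitors (23.0 ± 2.59 against 45.1 ± 18.4 CPM; SD, n = 5 each). Of 10 plasma cell genes, 9 did, with a median of -0.62 (camera adjusted p = 0.0035), among them Jchain, at 464 ± 280 against 897 ± 328 CPM. With an estimated correlation the adjusted p was 0.435 for the neutrophil list and 0.557 for the plasma cell list, and the neutrophil call was lost without EGF replicates 3 and 4 (camera adjusted p = 0.0556). That call was kept with EGF replicate 5 left out as well (median -1.08, camera adjusted p = 1.37e-06), in a fit where camera called more lists than with all 10 libraries. Saline replicate 1 had a lower neutrophil list mean (-1.76) than 4 of the EGF libraries, and the median of that list was -1.24 without EGF replicate 5, -0.41 without Saline replicate 3 and -0.39 without Saline replicate 4. The plasma cell median was -0.34 without EGF replicate 5.

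**Figure D2:**
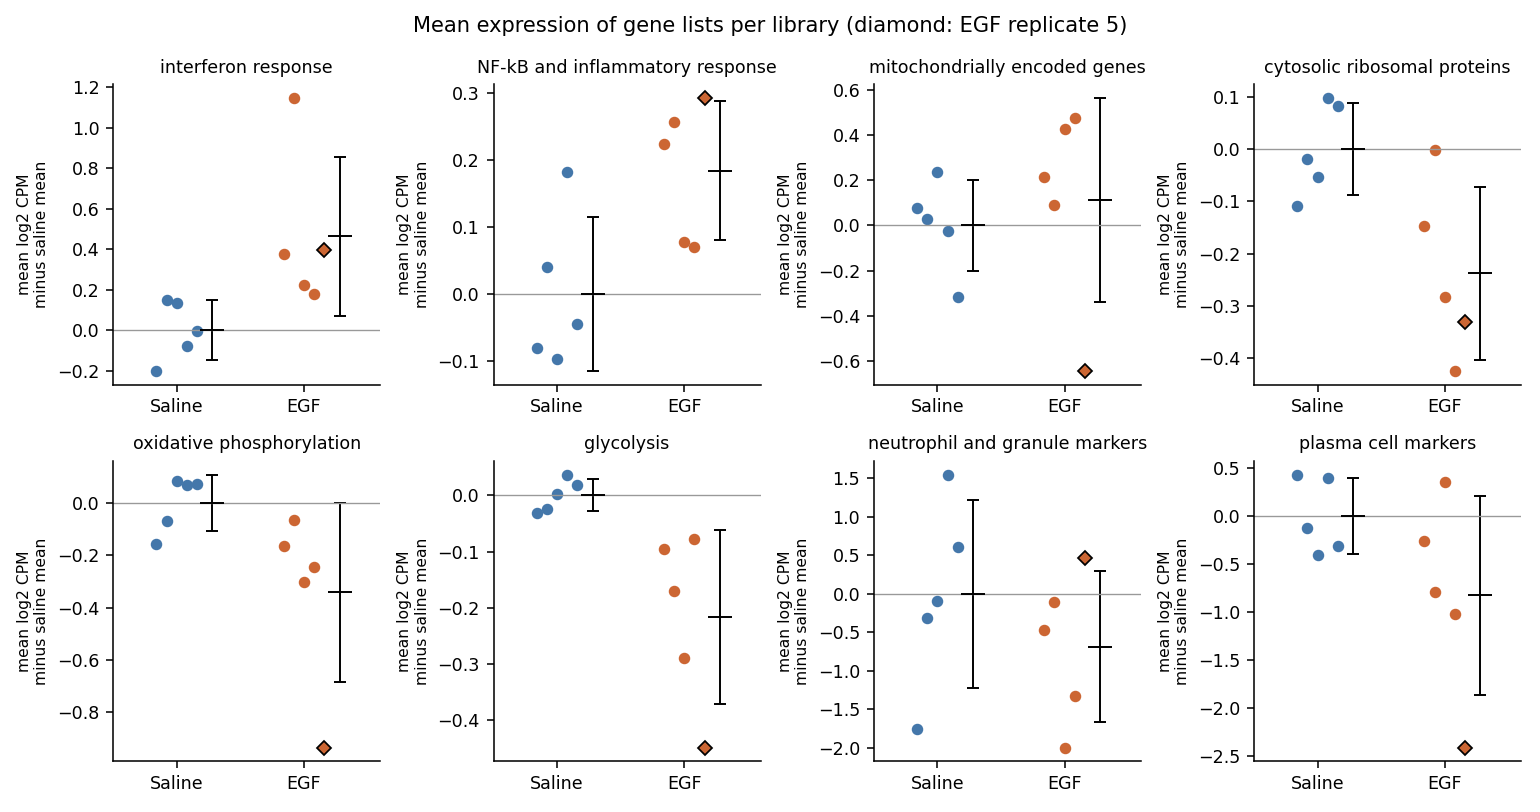
Mean log2 CPM of 8 gene lists in each library, relative to the mean of the saline libraries (vertical axes, each with its own scale), with saline libraries in blue and EGF libraries in orange; the bar and whiskers are the mean and SD of each group (n = 5), and the diamond is EGF replicate 5. EGF replicate 2 stands at 1.15 for the interferon list, and EGF replicate 5 is the lowest library for oxidative phosphorylation, glycolysis, plasma cell and mitochondrially encoded genes.

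The other 22 lists gave no camera call. Those for DNA repair had medians of 0.07 (non-homologous end joining, 17 genes, camera adjusted p = 0.415), 0.14 (homologous recombination, 25 genes, 0.415) and 0.08 (Fanconi anemia pathway, 16 genes, 0.415), and Trp53bp1, which favours end joining, had the smallest p in the first (log2 fold change 0.38, SE 0.12, edgeR adjusted p = 0.552). For p53 targets the median was -0.06 with a mean of 0.02 (34 genes, camera adjusted p = 0.819), and for the BCL2 family -0.18 (15 genes, 0.681), in which Bcl2l11, which encodes the killer BIM, passed adjusted over the list alone at 57.1 ± 13.2 against 35.0 ± 4.84 CPM (SD, n = 5 each). Among the p53 targets, Btg2 passed edgeR as higher when adjusted over the list alone, and DESeq2 called it over all genes (adjusted p = 0.0135). Cell cycle lists had -0.08 for S phase (30 genes, 0.236) and 0.05 for G2 and mitosis (34 genes, 0.50). HSC markers had 0.09 (28 genes, 0.415), HSC aging genes -0.13 (16 genes, 0.415), led by Clu (0.696 ± 0.465 against 2.25 ± 0.874 CPM), and multipotent and lymphoid-primed progenitor genes 0.01 with a mean of -0.05 (19 genes, 0.886). ERBB receptors and ligands had -0.14 with a mean of 0.15 (5 of 17 genes tested, 0.604), among them the Egf gene at 4.51 ± 1.88 against 2.19 ± 0.520 CPM. With 1 library left out the medians ranged from 0.03 to 0.09 for end joining and 0.03 to 0.18 for homologous recombination, both lowest without EGF replicate 5. They ranged from 0.01 to 0.09 for the Fanconi pathway, from -0.22 to -0.04 for the BCL2 family, from -0.10 to -0.04 for S phase. For HSC markers they ranged from 0.005 to 0.21 and for ERBB genes from -0.28 to -0.05.

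Of stress lists, the unfolded protein and integrated stress response had a median of -0.09 (camera adjusted p = 0.255), the hypoxia response -0.09 (0.415), and senescence and secretory genes -0.001 with a mean of 0.09 (0.415), in which the cell cycle inhibitor gene Cdkn1b was at 131 ± 16.7 against 106 ± 6.45 CPM (SD, n = 5 each). Markers of other cells had medians of -0.64 (B cells, camera adjusted p = 0.0762), -0.24 (monocytes and macrophages, 0.196), 0.20 (erythroid cells, 0.255), -0.12 (stroma and endothelium, 0.415), -0.02 with a mean of 0.07 (megakaryocytes and platelets, 0.681), -0.002 (dendritic cells, 0.735), -0.07 with a mean of 0.13 (T and NK cells, 0.832) and 0.25 with a mean of -0.12 (mast cells, basophils and eosinophils, 0.837). With 1 library left out the medians ranged from -0.46 to -0.05 for monocytes, both without a saline library, and from 0.08 to 0.35 for erythroid cells. They ranged from 0.06 to 0.30 for mast cells, from -0.20 to -0.04 for the unfolded protein response and from -0.19 to -0.06 for hypoxia. Pou2af1 led the B cell list at 12.6 ± 4.51 against 22.9 ± 8.78 CPM. Without EGF replicate 5 the camera calls were 5 higher and 13 lower, and adding to those named above were the B cell, monocyte, S phase and unfolded protein lists among the lower and the erythroid list among the higher (adjusted p = 0.0085, 0.0044, 0.0038, 0.0005 and 0.0110). With an estimated correlation none of these 18 calls held, the lowest adjusted p being 0.116.

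Of 7 measures of library composition, the share of ribosomal protein mRNA had the smallest p: it was 2.69% ± 0.232 of counts with EGF and 3.12% ± 0.126 with saline (SD, n = 5 each), with an exact two-sided permutation p of 0.0238, or 0.167 after adjustment over the 7. None of the 7 passed after adjustment. Mitochondrially encoded mRNA took 0.626% ± 0.140 against 0.496% ± 0.0688 (exact permutation p = 0.119), replication-dependent histones 0.321% ± 0.0423 against 0.369% ± 0.0392 (p = 0.0952, exact), and the top 10 genes 23.9% ± 2.34 against 25.2% ± 0.846 (p = 0.333, exact). Hemoglobin genes took 0.0005% in both groups (exact p = 0.968). Total counts were 7707265 ± 521193 against 7801616 ± 323698 (exact p = 0.778). The number of genes detected was 18240.4 ± 3125 with EGF and 19602 ± 267 with saline (exact p = 0.540), and without EGF replicate 5 the difference turned to 15.6 genes more with EGF.

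**Figure D3:**
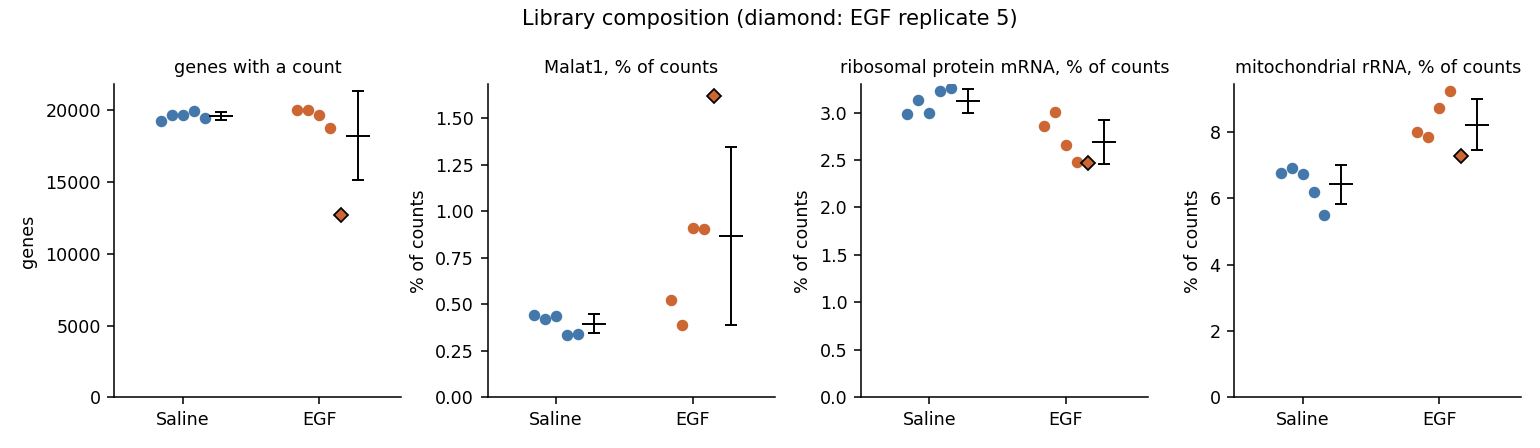
Number of genes with a count and the percentage of each library's counts in Malat1, ribosomal protein mRNA and mitochondrial rRNA (vertical axes from 0), with saline libraries in blue and EGF libraries in orange; the bar and whiskers are the mean and SD of each group (n = 5), and the diamond is EGF replicate 5. EGF replicate 5 has 12731 genes with a count and the highest Malat1 share, 1.62%.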

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

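A group was singled out where 1 library's gap to its neighbour took over 0.71 of the group's range; 17 of 190 groups of 5 were, where chance gives about 1 in 20, or 9.5, and in 10 of the 17 that library was EGF replicate 5. The tests on unsampled genes and on GC content and transcript length were chosen after the results were seen.

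EGF replicate 5 stood apart, with 12731 genes detected against 18734 to 20046 elsewhere (gap 0.821 of the range) and a median correlation of 0.814 with the other libraries, whose own medians were 0.955 to 0.969. GC content and transcript length together accounted for 1.65% of its deviation from the other EGF libraries over genes. That small share argues against such a bias as the main source of its deviation. In the rest they accounted for 0.48% to 2.06%. Each share is of a library's own deviation, so the shares do not compare the size of a bias between libraries. In it 0 genes reached 50 CPM while under 1 CPM in each other library. That argues against RNA from a source with abundant genes absent from the other libraries. Cell types whose RNA is also present in the other libraries could not be seen this way. A small number of sampled RNA molecules may account for how EGF replicate 5 stood apart. In it 1102 genes averaging 20 or more counts in the other libraries had 0 counts, against 15 to 58 in any other library. Its total of 7781772 counts lay within the range of the others. A sample of the same cell type from elsewhere stays open. No biological explanation was tested, since the labels set this library in the same group as 4 others.

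The same library was high for Xrcc4 (25.6 CPM, next 10.4; gap 0.842), Mki67 (2306 CPM, next 1671; gap 0.803), Angpt1 (798 CPM, next 429; gap 0.966), Cdkn1b (160 CPM, next 129; gap 0.736) and Mx1 (67.0 CPM, next 14.8; gap 0.828). It was low for Ebp (3.64 CPM, next 12.2; gap 0.824), Msmo1 (6.02 CPM, next 9.15; gap 0.861), and the mean log2 CPM, relative to saline, of cholesterol synthesis (-1.74, next -0.26; gap 0.908) and oxidative phosphorylation genes (-0.94, next -0.30; gap 0.729). EGF replicate 2 was high for the mean of the interferon list (1.15, next 0.40; gap 0.778). EGF replicate 1 was high for Ighv1-75 (1.0 CPM, next 0.129; gap 0.872). Total counts were low in EGF replicate 3 (6805106, next 7781772; gap 0.75) and high in Saline replicate 3 (8370820, next 7732068; gap 0.81). Saline replicate 4 was low for Procr (6.86 CPM, next 10.5; gap 0.768) and high for Rpl35 (357 CPM, next 328; gap 0.712), and Saline replicate 1 was low for Sod2 (58.1 CPM, next 65.0; gap 0.722).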

How the results depend on the processing

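The fits without EGF replicates 3 and 4, without replicates 3 to 5, and without replicate 5 in combination were chosen after the data were seen. The counts of called genes, 1 higher and 0 lower, were the same with RLE, upper quartile scaling, limma-voom, no filter, the filter of 1 CPM and the robust fit. They were 0 and 0 with library size only, 13 and 15 with DESeq2, 8 and 4 with limma-voom and quality weights, 7 and 12 with 1 surrogate variable, and 0 to 4 higher and 0 to 4 lower with 1 library left out, most without EGF replicate 5. With the replicate block they were 0 and 0 (Cd69 adjusted p = 0.781, log2 fold change 0.83). Over all genes the replicate numbers gave no sign of pairing. Deviations of same-numbered libraries from their group means correlated at -0.08 to 0.02, and 1 of 5 pairs correlated best with its own number. The labels state no pairing, but one that touches few genes is not excluded. Over replicates 1 to 4, the counts were 0 and 0 with the replicate block and 2 and 3 without it. Cd69 had a log2 fold change of 0.73 to 0.88 over all settings, with an adjusted p between 5.81e-10 (DESeq2) and 0.781. Without EGF replicates 3 and 4 the counts were 0 and 0, and without replicates 3 to 5 they were 1 and 0 (Cd69 0.73, adjusted p = 0.131, so the gene was another). Without EGF replicate 5 they were 172 and 132 by DESeq2, 134 and 118 with no filter, 14 and 11 with the robust fit, 5 and 1 with quality weights, 4 and 1 with limma-voom, and 1 and 0 with 1 surrogate variable; with a further library left out they lay between 1 and 0 (without Saline replicate 3, EGF replicate 3 or EGF replicate 4) and 21 and 27 (without Saline replicate 1). The lists called, 4 higher and 9 lower, became 0 and 0 with an estimated correlation, 1 and 1 by fry, 9 and 11 without EGF replicates 3 to 5, and 3 and 5 without replicates 3 and 4; scaling, filter, block, ranks and single libraries left out gave 3 to 5 higher and 8 to 13 lower. Of 1610 values of single genes under alternatives 1530 held their direction and side of the threshold, 40 passed it, 11, all of Cd69, no longer did, and 29 changed sign. Of 630 list medians 534 held, 18 gained a call, 36 lost one and 42 changed sign. No sign change was in a gene or list called in the main test. With quality weights the log2 fold changes were 0.192 for Bbc3, -0.056 for Xrcc4, 0.015 for Ly6a, 0.027 for Procr and 0.060 for Flt3. Flt3 was at 0.006 with limma-voom, 0.001 with the replicate block and 0.023 with 1 surrogate variable, where Xrcc4 was at -0.013. Without EGF replicates 3 to 5 they were 0.039 for Bbc3, -0.067 for Cdkn1a, -0.078 for Mdm2, -0.020 for Prkdc, -0.108 for Xrcc4, 0.433 for Ly6a, 0.163 for Procr and 0.164 for Flt3; without replicates 3 and 4, Ly6a was at 0.043 and Flt3 at 0.049. Leaving out 1 library gave -0.428 to 0.131 for Bbc3, -0.102 to 0.064 for Flt3, -0.474 to 0.049 for Ly6a, -0.548 to 0.025 for Procr and -0.086 to 0.511 for Xrcc4. It gave list medians of -0.204 to 0.006 (HSC aging), -0.248 to 0.318 (T and NK cells), -0.486 to 0.015 (stroma and endothelium), -0.027 to 0.111 (G2 and mitosis), -0.156 to 0.140 (dendritic cells), -0.142 to 0.125 (megakaryocytes), -0.064 to 0.068 (multipotent progenitors), -0.087 to 0.013 (p53 targets) and -0.048 to 0.096 (senescence). With RLE the senescence median was 0.007 and the dendritic 0.003, which was 0.001 with the filter of 1 CPM. Without EGF replicates 3 to 5 the medians were 0.211 (ERBB), -0.020 (end joining), 0.088 (senescence), 0.050 (hypoxia), 0.174 (megakaryocytes), 0.199 (dendritic cells), 0.395 (T and NK cells) and -0.057 (mast cells and eosinophils), of which camera called the megakaryocyte, dendritic and T and NK lists higher (adjusted p = 0.0180, 2.90e-05 and 0.0007); without replicates 3 and 4 they were 0.084 (senescence), 0.006 (megakaryocytes) and -0.236 (mast cells and eosinophils). The EGF minus saline difference with 1 library left out was -1813 to 15.6 genes detected, -7.05e-05 to 0.000117 percentage points of hemoglobin and -194511 to 131190 total counts. Fewer libraries in a fit lower its power at a given spread between libraries. On simulated counts 68% of 2-fold changes were recovered with the dispersions estimated without EGF replicate 5, against 52% with those of all 10 libraries. Each simulation gave all its libraries the same dispersions. This difference thus follows from those estimates, and does not measure the power of the real test with the outlying EGF replicate 5 in it. The common biological coefficient of variation by edgeR was 0.183 without that library and 0.374 with it. Beyond that, the cause of the changes was not tested. At this depth Egfr, with 0 to 2 counts per library, could not be compared.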

Other observations

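Of the tests reported here, those of the 5 added shares of library counts, of AI506816 and the mean list scores, of the T and NK cell sum, of the immediate early genes, of the fits without EGF replicates 3 to 5 and of the other splits of the libraries were chosen after the results were seen. In the mast cell, basophil and eosinophil list, 9 of 14 genes had a log2 fold change above 0 (median 0.25, camera adjusted p = 0.837), but Epx, the eosinophil peroxidase gene, was at 13.2 ± 2.24 against 48.3 ± 27.4 CPM (SD, n = 5 each; log2 fold change -1.87, SE 0.42, edgeR adjusted p = 0.552, DESeq2 0.0111), passed edgeR adjusted over its list alone, and was at 11.7 CPM in Saline replicate 1, within the EGF range of 10.1 to 15.8. Prg2, the major basic protein gene, was at 58.6 ± 18.7 against 130 ± 84.9 CPM, with Saline replicate 1 (29.3 CPM) below all EGF libraries (41.4 to 81.8 CPM). Immunoglobulin genes together took 0.655% ± 0.329 of counts with EGF and 1.12% ± 0.401 with saline (exact permutation p = 0.0873, 0.0873 after adjustment over 5 measures), and Ighm was at 1662 ± 894 against 3078 ± 1592 CPM. AI506816, a non-coding RNA, had the second smallest p of all genes with all 10 libraries, at 177 ± 13.7 against 247 ± 7.89 CPM (log2 fold change -0.48, edgeR adjusted p = 0.240).

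Mitochondrial rRNA took 8.21% ± 0.771 of counts with EGF and 6.42% ± 0.585 with saline (SD, n = 5 each). It was higher in 5 of 5 EGF libraries than in any saline library. The exact permutation p was 0.0079, the smallest possible, and 0.0397 adjusted over the 5 measures added after the data were seen. Depletion of rRNA preceded library making, and how complete it was in each library is not known. The nuclear non-coding RNA Malat1 took 0.868% ± 0.479 against 0.396% ± 0.0527 (exact permutation p = 0.0317, adjusted 0.0529), with 0.905% to 1.62% in EGF replicates 3, 4 and 5 and 0.387% and 0.521% in replicates 2 and 1. Malat1, Neat1 and Kcnq1ot1 together took 0.958% ± 0.522 against 0.440% ± 0.0595 (exact permutation p = 0.0317, adjusted 0.0529), with 1.01% and 1.03% in EGF replicates 3 and 4 and 1.76% in replicate 5. Neat1 was at 867 CPM and Kcnq1ot1 at 659 CPM in EGF replicate 5, their highest values of the 10 libraries. Rn7sk and Xist, also nuclear, were not raised like this in EGF replicate 5: Rn7sk took 0.169% there, against 0.213% and 0.295% in EGF replicates 3 and 4 and 0.139% to 0.167% with saline. Xist took 0.189%, against 0.295% and 0.290% in EGF replicates 3 and 4 and 0.183% to 0.243% with saline. The abundant non-coding features, Gm23935, Gm26917 and Gm42418, together took 13.3% ± 2.97 against 16.7% ± 1.36 (exact permutation p = 0.0556). Mean list scores compared by exact permutation gave p = 0.0079 for interferon, glycolysis and cholesterol synthesis, and 0.0926 after adjustment over 35 lists, so none passed. By the same exact test p was 0.0159 for antioxidant genes, 0.0238 for oxidative phosphorylation, 0.0317 for NF-kB, 0.0397 for ribosomal proteins, 0.0476 for heat shock and 0.0635 for histones, with 0.139 to 0.222 after adjustment. Among the remaining lists that camera called, it was 0.627 for mitochondrially encoded genes, 0.492 for ERK-responsive genes, 0.357 for neutrophil genes and 0.135 for plasma cell genes.

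Ribosomal protein mRNAs had a median log2 fold change of -0.23, and part of this may come from the 3 libraries with a high Malat1 share: without EGF replicates 3 to 5 the median was -0.072. Transcript length and expression level were not settled as a cause, because 0.32% of 10000 random lists matched on both were as low, between the bounds set for either outcome. Those lists had a median of -0.11 themselves, so length and level may account for part of the shift. The observed median lay below their central 95%, which ran from -0.197 to -0.002. An effect of EGF in 3 of the 5 samples stays open, since the libraries with high Malat1 all carry the EGF label.

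Cd69, Ccl3, Btg2, Nlrc5 and Nr4a2 were higher in every EGF library than in any saline library. Whether the 3 libraries with a high Malat1 share are the cause cannot be judged from these genes. They were named for the smallest p over the same 10 libraries, so EGF replicates 1 and 2 were high in them partly by that choice. The median of the 5 log2 fold changes was 0.633 without the 3 libraries and 0.83 with all. More T and NK cells cannot be told apart from the other explanations: the summed CPM of their list with EGF was 0.891 times that with saline, but 1.17 times without EGF replicate 5 and the most abundant member, Nkg7 (25 against 42.3 CPM), and Il2rb (18.7 against 9.76 CPM) and Bcl11b (3.0 against 0.898 CPM) were higher, and without EGF replicates 3 to 5 camera called the list higher (median 0.395, adjusted p = 0.0007). That fit held EGF replicates 1 and 2 only, and camera called 9 lists higher in it. Handling before lysis cannot be told apart either, since Fos, Fosb, Jun, Junb, Egr1, Ier2, Dusp1 and Zfp36, chosen after the results, had a median log2 fold change of 0.053, while Nr4a1 (0.80) and Fosl2 (0.71) of the same fixed list were higher. An effect of EGF and a shift in which HSPC subsets were sorted also stay open and untested; Egfr itself had 0 to 2 counts per library.

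Chance could not be excluded for the count of genes with all 10 libraries: 5 of 100 splits of the libraries, the real one included, called 1 gene or more, and the highest other called 2. At an unadjusted p under 0.05, 1142 genes or more were reached by 2 of 100 splits, with 1243 in the other. With EGF replicate 5 left out, 2066 or more were reached by 2 of 100, with 2100 in the other. The 13 lists were reached by 7 of 100 splits, with up to 15 in another. Without EGF replicate 5, 2 of 100 splits called 8 genes or more, a share under 0.05; this excludes chance only weakly, since of the 10 libraries the one left out was that which gave the most calls, and leaving out 1 more brought the count as low as 1. The other set Saline replicate 1 with EGF replicates 1 to 4 and called 39, several times the real count. That split moves 1 library only, and with Saline replicate 1 left out as well the labelled groups gave 21 higher and 27 lower. It thus cannot tell an atypical Saline replicate 1 from a structure of the samples beside the groups. The 18 lists called without EGF replicate 5 were reached by 9 of 100 splits, with up to 21 in another.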
